A study of Homo sapiens with 9 samples.

How the data were processed

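RPMI-8402 is a human T-cell acute lymphoblastic leukaemia (T-ALL) cell line. ChIP-seq, which sequences the DNA recovered with an antibody from crosslinked and sheared chromatin, was run on 9 samples of this line. In 8 of them the antibody was directed against NKX2-1 (also called TTF1), a homeodomain transcription factor. These 8 libraries came from 4 wild-type (WT) clones, named WT10, WT13, WT28 and WT30, and from 4 clones named C12, C15, S04 and S36. The genotype field of the last 4 reads NKX2-1, and the series design text calls them knockout clones; they are called knockout clones here on the strength of that text. The last sample is a single library made with an antibody against acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers. Its genotype field also reads NKX2-1, no clone is named for it, and it has no replicate. Each clone contributed 1 library, so the p-values of tests over the 8 libraries measure the spread between clones. They cannot separate it from technical spread between libraries. The p-values of tests over genes, sets of regions, peaks or random placements measure no spread between clones.

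Per the submitters' processing notes, the tools used were FastQC, Bowtie2, SAMtools, MACS2 and deepTools and the genome build was hg38; versions, parameters and the control used for peak calling were not given in the sources used here. The authors deposited a list of called peaks for each sample, a combined peak list for the NKX2-1 antibody libraries, and a list of regions described as WT only. In the peak lists each peak carries its position, a score, a ratio (fold enrichment at the summit over the background the peak caller used), the −log10 of a p-value (not used) and of a q-value, and the distance of the summit from the peak start, in the layout in which MACS2 writes peaks, as checked on the deposited values. The score was 10 times the −log10 q in the deposited files, cut to a whole number, and was not used. The ratio and the −log10 q are the authors' own values and were used only to describe, rank or filter peaks within a list, and the −log10 q in 1 rank correlation. The smallest deposited −log10 q lay just above 2 in each library. Which libraries served as treatment and which as control for the combined list is not stated, and read numbers and sequencing depth are unknown because the peak lists hold none. A site without a peak is therefore a site that was not called at the depth of that library, not a site shown to be unbound. No pair among the 8 libraries had the same peak list; the highest Jaccard index of any pair was 0.638.

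Peaks on chromosomes 1 to 22, X and Y were used, and all sequences in the files were an alternative. Coordinates are 1-based on hg38. Overlaps were counted from 1 bp. Peaks of the 8 libraries were merged into union regions where they overlapped by 1 bp or more. The Jaccard index of a pair of libraries is the number of base pairs covered in both divided by the number covered in either. Gene positions came from a RefSeq gene table for the GRCh38.p14 assembly, the assembly that hg38 names, with 20033 protein-coding genes on these chromosomes. The table gives gene starts and ends without strand or exons, so whether a peak within a gene is exonic, intronic or in a UTR was not determined, and a symbol given for a peak outside genes is that of the nearest protein-coding gene. A peak was assigned to a gene within 10 kb of the gene body.

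Values per library were compared with a two-sided exact permutation test of the difference of the 2 group means over all 70 assignments of the 8 libraries. The smallest p it can give is 0.0286. Similarity within against between genotypes was tested one-sided over the 35 splits of the libraries into 4 and 4. Benjamini-Hochberg adjustment covered these 9 tests. Among them, 2 use the combined and WT-only lists, which were made from these same libraries. Their small p-values lower the adjusted p of other tests. Each union region was tested with a two-sided Fisher's exact test, and a region called in 3 or 4 libraries of one genotype and 0 of the other was termed WT-specific or knockout-specific. The numbers of such regions were set against the other splits. Overlap with H3K27ac was compared with 1000 random placements of the same regions on the same chromosomes, one-sided. Assembly gaps, stretches without known sequence, were not left out of the placements because no genome sequence was used. The 11 gene lists, with 248 symbols that all matched the gene table, were tested with two-sided Fisher's exact tests against all other protein-coding genes. The lists cover T-ALL oncogenic transcription factors, RUNX1 and haematopoietic partners, T-cell development and identity, NOTCH and MYC targets, DNA damage response and repair, apoptosis and survival, cell cycle, lung and thyroid targets of NKX2-1, B-cell and myeloid lineage, histone genes, and JAK-STAT and cytokine signalling. Shares of regions carry 95% Wilson intervals, and a share of 0 carries the limit that 3 counts set; both cover counting error only.

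The groups, main tests, gene lists, most alternatives and the rule for named regions were fixed before the data were examined. The plan did not include the Spearman correlation or the test of peaks on other sequences. Nor did it include the list of knockout regions without a WT peak and the comparisons made with it. The rule named the 15 combined-list peaks with the highest fold enrichment, the 10 WT-only regions called in the most WT libraries, union regions called in all 4 libraries of one genotype and none of the other up to 15 per direction, up to 10 members of each gene list with a combined-list peak, and the NKX2-1 and RUNX1 loci. Some regions and genes that this rule names are not reported here. Planned counts of NKX2, RUNX and other motifs at the summits need a genome sequence and were not run. The planned share of peaks at transcription start sites needs strand, and was replaced, after the data were examined, by the share of summits within 1 kb of either end of a protein-coding gene and the share within gene bodies. The nearest protein-coding gene took the place of the nearest start site in the same way, and the comparison of genes near peaks with random placements was also added after the data were examined. The alternatives were stricter peak thresholds (−log10 q of 5 and of 10), the 500 strongest peaks of each library, all sequences, removal of regions called in all 8 libraries, a 50% overlap, other definitions of a genotype-specific region, another similarity measure, other gene distances and backgrounds, and leaving out each library; H3K27ac overlap without WT10, S36 or both was added after the data were examined.

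The region counts were tested on simulated data built from the union regions. Among 1614 simulated regions, 200 were planted as WT-only with a detection rate of 90% per WT library. Of these, 196 drew calls in 3 or 4 WT libraries and all 196 were recovered as WT-specific (98% of those planted), while 5 unplanted regions were called WT-specific and 11 knockout-specific. Recovery of the 196 follows from the definition and checks the counting only. The 98% follows from the rate that was set. The WT libraries called 3.35% to 57.9% of combined-list peaks, so it does not measure sensitivity in these data. Unplanted regions were drawn at the same rate in all libraries, so clones with many regions of their own were not modelled. None of the planted regions passed an adjusted Fisher's exact test, since a single region in 4 against 4 libraries cannot give an unadjusted p below 0.0286. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.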

Results

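The question set by the design was where NKX2-1 binds in RPMI-8402 cells. NKX2-1 peaks were called in 4 WT clones and 4 knockout clones. The 4 knockout libraries held 810 (C12), 817 (C15), 842 (S04) and 934 (S36) peaks on chromosomes 1 to 22, X and Y. The 4 WT libraries held 1144 (WT10), 742 (WT13), 875 (WT28) and 771 (WT30). Between 254 and 325 further peaks per library lay on other sequences of the assembly. The H3K27ac library held 9857 peaks on the same chromosomes, with 38.2% of their summits lying within 1 kb of an end of a protein-coding gene. Sequencing depth is unknown for every library.

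The NKX2-1 and RUNX1 loci carried no NKX2-1 peak in either genotype. At NKX2-1 itself (chromosome 14, 36516397 to 36520232), the gene targeted in the knockout clones, 0 peaks were called within the gene or 10 kb to either side in all 8 libraries, in the combined list and in the WT-only list. The H3K27ac library had 4 peaks in this window, of which 2 lay in the gene; the strongest (36518304 to 36518826) had a 6.92-fold enrichment. RUNX1 (chromosome 21, 34787801 to 35049302), a core haematopoietic transcription factor that the series title names beside NKX2-1, likewise had 0 peaks in the 8 NKX2-1 libraries and in both lists. It carried 25 H3K27ac peaks, the strongest with 11.6-fold enrichment. Peak lists show no deletion, so the locus neither supports nor contradicts the genotype of any clone.

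The authors' combined list held 209 peaks, of which 126 were called in at least 1 WT clone, 0 in a knockout clone and 83 in none of the 8 libraries. Its strongest peak lay within TRIM14, a tripartite motif protein gene (chromosome 9, 98101978 to 98102355, 9.34-fold, −log10 q 68.8), and was called in all 4 WT libraries and 0 of the 4 knockout libraries. The same 4 against 0 held for a peak within the deubiquitinase gene USP20 (chromosome 9, 129863063 to 129863570, 8.19-fold), one 120576 bp from MYLK4 (chromosome 6, 2542847 to 2543249, 8.05-fold) and one 276833 bp from C1orf174 (chromosome 1, 4176804 to 4177342, 7.31-fold). Peaks 30382 bp from TMEM174 (chromosome 5, 73205343 to 73205718, 9.31-fold), within NOSIP (chromosome 19, 49568078 to 49568492, 7.21-fold) and 10318 bp from KRT2 (chromosome 12, 52662346 to 52662671, 6.96-fold) were called in 3 WT libraries. Peaks 543482 bp from KRABD4 and 30492 bp from PSMB1, which encodes a proteasome subunit, were also called in 3. Those nearest to OLFM1, the Wnt receptor gene FZD7 and SLC44A1 were called in 2, and those nearest to TSN and the fibronectin gene FN1 (245293 bp away) in 1.

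Across the list, WT10 had a call at 121 of the 209 peaks (57.9%, 95% Wilson interval 51.1 to 64.4), WT28 at 57 (27.3%, 21.7 to 33.7), WT30 at 35 (16.7%, 12.3 to 22.4) and WT13 at 7 (3.35%, 1.63 to 6.75). Each knockout library had 0 of 209, which allows a share of up to 1.44%. The mean was 26.3% ± 23.2 (SD, n = 4) in WT and 0% in knockout clones (n = 4), with p = 0.0286 in the exact permutation test, the smallest it can give, and 0.0857 after adjustment over 9 tests. The list was made from these same libraries, so this difference is not independent evidence, and the WT mean without WT10 was 15.8%. The authors' −log10 q of a peak rose with the number of WT libraries that called it, from a median of 7.95 for the 83 peaks called in no library to 38.5 for the 6 called in all 4 (Spearman's rho = 0.503 across peaks, permutation p = 0.0005, the smallest that 2000 permutations can give). Peaks are not independent replicates. The −log10 q also comes from a list made from these libraries, so a rise may follow from how the list was made.

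**Figure D1:**
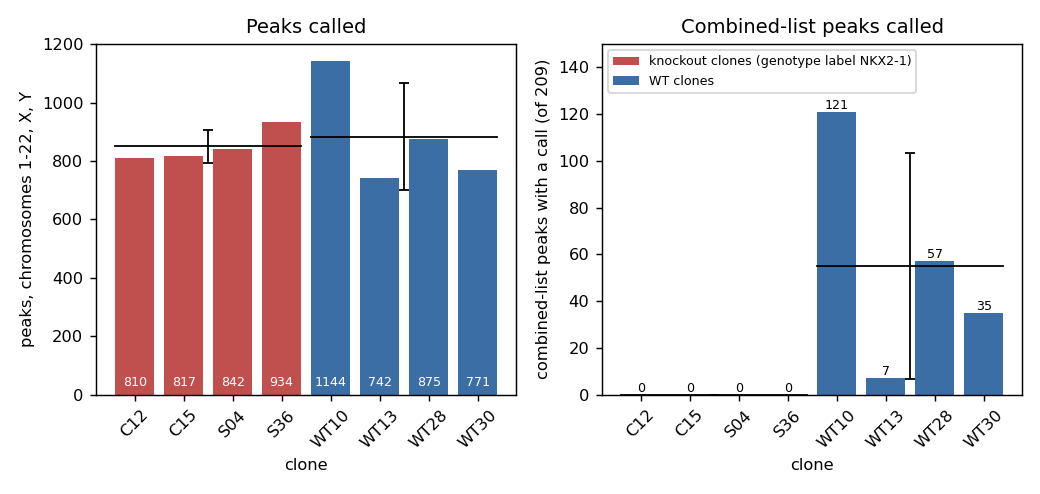
Peaks called per clone on chromosomes 1 to 22, X and Y (left axis, number of peaks) and the number of the 209 combined-list peaks with a call in each clone (right panel axis, number of peaks); horizontal lines are group means and error bars are 1 SD (n = 4 clones per genotype). Peak numbers overlap between genotypes, while combined-list peaks were called in 121, 7, 57 and 35 instances in the WT clones and in 0 in each knockout clone.

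**Figure D2:**
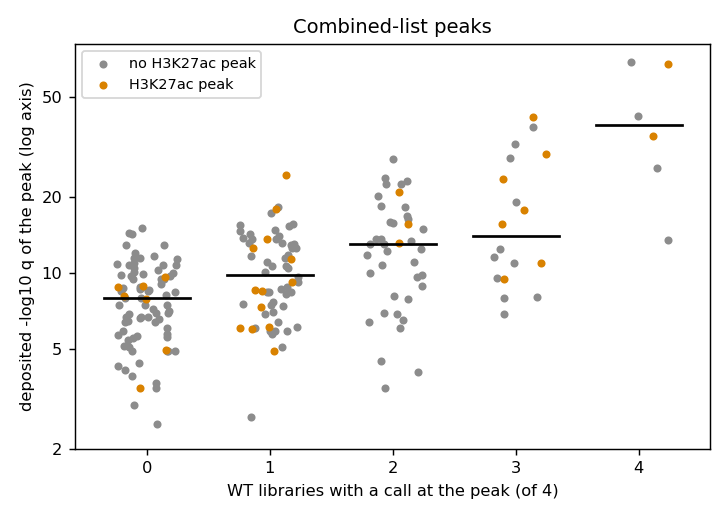
Each point is 1 of the 209 combined-list peaks, placed by the number of WT libraries with a call there (horizontal axis, with random sideways spread) and its deposited −log10 q (vertical log axis); black lines are medians and orange points overlap an H3K27ac peak. The medians run from 7.95 for peaks called in no library to 38.5 for those called in all 4 WT libraries.

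Most combined-list peaks lay away from gene ends. Summits of 98 peaks (46.9%, 95% Wilson interval 40.2 to 53.7) lay within protein-coding genes, 13 (6.22%, 3.67 to 10.3) within 1 kb of a gene end, and 58 (27.8%) over 50 kb from any protein-coding gene. Chromosome 2 held 29 peaks, chromosome 1 held 27 and chromosome 8 held 17, with 0 on chromosomes 13, 18 and Y. An H3K27ac peak overlapped 32 combined-list peaks (15.3%, 11.1 to 20.8), among them those in USP20 and nearest to KRABD4, C1orf174, TSN, KRT2 and OLFM1. Of these 32, 1 lay within 1 kb of a gene end. Random placements gave 0.313% ± 0.401 (SD of 1000 placements; permutation p = 0.000999, the smallest they can give). The placements were uniform along each chromosome, so they do not account for how readily a stretch of chromatin is sequenced.

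Few members of the fixed gene lists had a combined-list peak nearby. The T-ALL oncogenic transcription factor list had 1 of 24 genes, HHEX, with a peak in the gene (chromosome 10, 92690798 to 92691010, 3.34-fold) that overlapped H3K27ac and was called in WT10. RUNX2 was the 1 hit among 16 RUNX1 partner factors (chromosome 6, 45488973 to 45489172, 2.58-fold), at a peak called in none of the 8 libraries. CCND3, which encodes cyclin D3, accounted for 1 of 12 NOTCH and MYC targets and 1 of 26 cell cycle genes (chromosome 6, 42045740 to 42045957, 3.53-fold, called in WT10). The T-cell development list had 1 of 36 genes with a peak and the lung and thyroid list 1 of 24.

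DNA damage response and repair genes had 0 of 47, apoptosis and survival genes 0 of 16, B-cell and myeloid genes 0 of 20, histone genes 0 of 20 and JAK-STAT genes 0 of 16. None of the 11 lists passed the adjusted Fisher's exact test (smallest adjusted p = 0.388), and 0 had an unadjusted p under 0.05. In all, 149 protein-coding genes lay within 10 kb of a combined-list peak, against 125 ± 9.74 (SD) for 1000 random placements (permutation p = 0.00599). The placements could fall in assembly gaps, where no peak can be called, which lowers the random count. This p therefore does not show a preference for genes. Random placement put 0.356 ± 0.593 (SD) genes of the DNA repair list near a peak, so lists of this size cannot show a shortage.

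The list described as WT only held 561 regions, 496 of them on chromosomes 1 to 22, X and Y. All 561 were identical to the merged peaks of the 4 WT libraries that no knockout peak overlapped, so their absence from knockout libraries is by construction. The 10 named by rule lay at TRIM14 and USP20, within ZNF652 (chromosome 17, 49342138 to 49342651) and nearest to C1orf174, MYLK4, GFRA2 (chromosome 8, 21484100 to 21484531), CWH43, PGBD2, LINC02798 and SPATA31A5, each called in 4 WT libraries. Distances to the gene were 206082 bp for GFRA2, 230192 bp for CWH43, 15804 bp for PGBD2, 3703192 bp for LINC02798 and 344494 bp for SPATA31A5. Those nearest to LINC02798, CWH43 and SPATA31A5 held no combined-list peak and lay only 282, 241 and 1380 bp from a knockout peak. Of the 561, 370 (66.0%) were called in a single WT library and 73 in 3 or 4. The mirror list, knockout peaks without a WT peak, held 440 regions, of which 329 were called in 1 library. A difference between mirrored lists as large as 561 against 440 arose in 18 of the 35 splits.

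A combined-list peak lay in 126 of the 561 WT-only regions (22.5%) and in 0 of the 440 mirror regions, which allows a share of up to 0.682%. None of the 1147 union regions with a call in a knockout library held a combined-list peak. The 0 among mirror regions may therefore be fixed by how the list was made, and the contrast is not independent evidence. H3K27ac overlapped 61 of the 496 WT-only regions on chromosomes 1 to 22, X and Y (12.3%, 95% Wilson interval 9.69 to 15.5) and 28 of the 415 mirror regions (6.75%, 4.71 to 9.58; Fisher's exact p = 0.00504 over regions, which are not independent replicates). The 2 clones with the most regions of their own weighed on this comparison. Without WT10 the shares were 8.07% and 7.05% (Fisher's exact p = 0.669), without S36 12.3% and 0.532% (p = 3.32e-08, Fisher's exact test) and without both 8.01% and 2.08% (p = 0.00211, Fisher's exact test). These settings were chosen after seeing the data. Random placements of the WT-only regions gave 0.313% ± 0.252 (SD; permutation p = 0.000999, the smallest that 1000 placements can give). WT libraries called on average 37.6% ± 26.1 (SD, n = 4) of the 496 regions and knockout libraries 0%, with an exact permutation p of 0.0286 that the construction of the list fixes. Near WT-only regions the fixed lists held TG (lung and thyroid targets), STAT3 and STAT5A (JAK-STAT), CCND3 and CDK6 (cell cycle), HHEX and BLK, among others. None of the 11 lists passed adjustment (smallest adjusted p = 0.107 by Fisher's exact test; 3 lists at unadjusted p under 0.05). The mirror list held NOTCH1, ETS1, ETV6, LCK, FAS, CD79A and JAK1, among others, again with no list past adjustment (smallest adjusted p = 0.156 by Fisher's exact test; 1 list at unadjusted p under 0.05).

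Regions called repeatedly in one genotype were found in both directions. All 4 WT libraries and no knockout library had a call at 13 regions. Beyond those at the 10 sites named above they included ART1 (chromosome 11, 3654136 to 3654571) and regions nearest to LOC124905368 (24805 bp away) and ZNF33B (506924 bp away). The regions nearest to LOC124905368 and ZNF33B held no combined-list peak and lay 1767 and 55 bp from a knockout peak. All 4 knockout libraries and no WT library had a call at 6 regions, a number that 1 of the 34 other splits of the libraries also reached. The strongest of these, 19832 bp from CIMIP5 (chromosome 2, 11112665 to 11113927), had a mean deposited enrichment of 10.99-fold in the libraries that called it. The others lay within TRPV3, an ion channel gene (chromosome 17, 3535038 to 3535634), 1233 bp from the forkhead factor gene FOXK1 (chromosome 7, 4680576 to 4681547), 10586 bp from GIMAP5, a gene of lymphocyte survival (chromosome 7, 150753963 to 150754500), and nearest to TP53TG3B (23068 bp away) and WSB1 (1724869 bp away). The region nearest to TP53TG3B lay 635 bp from a WT peak.

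Counting regions with 3 or 4 libraries against 0, 66 of the 1643 union regions were WT-specific and 33 knockout-specific; the highest count in one direction among the other splits was 43, and 4 of those 34 splits gave 33 or more. Of the 66, 25 held a combined-list peak, and 10 of those 25 overlapped H3K27ac; none of the 25 lay within 10 kb of a knockout peak. The other 41 had 0 overlaps with H3K27ac, and 27 of them lay within 10 kb of a knockout peak. The 33 knockout-specific regions had 0 combined-list peaks and 0 overlaps with H3K27ac, each of which allows a share of up to 9.09%, and 10 lay within 10 kb of a WT peak. Their lack of combined-list peaks may be fixed by how that list was made. No single region passed adjustment in Fisher's exact test (0 of 1643, smallest adjusted p = 1; 19 at an unadjusted p under 0.05, each at the smallest possible value of 0.0286). The excess of WT-specific over knockout-specific regions was lost among stronger peaks: at a −log10 q of 10 or more there were 19 WT-specific and 22 knockout-specific regions, and among the 500 strongest peaks of each library 20 and 20. The highest count in one direction among the other splits was 14 and 13 in these settings. Those splits were examined after the results were seen. Leaving out WT10, WT13, WT28 or WT30, which then requires all 3 remaining WT libraries, left 18, 47, 20 and 20 WT-specific regions. Leaving out C12, C15, S04 or S36 in the same way left 11, 14, 14 and 14 knockout-specific regions. No protein-coding gene of the 11 lists lay within 10 kb of a WT-specific or knockout-specific region (0 lists at unadjusted p under 0.05 by Fisher's exact test).

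**Figure D3:**
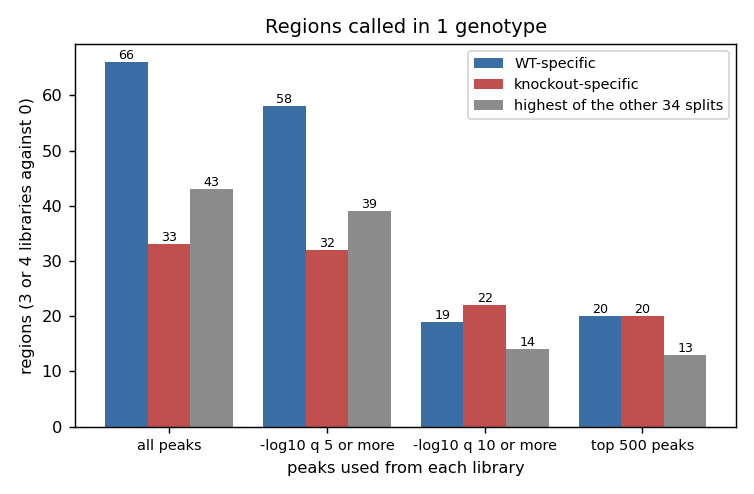
Number of regions (vertical axis) called in 3 or 4 libraries of one genotype and 0 of the other, for all peaks, peaks with a −log10 q of at least 5 or 10, and the 500 strongest peaks of each library; grey bars give the highest count in one direction among the other splits of the 8 libraries. With all peaks 66 WT-specific regions stand against 33 knockout-specific ones, and with the 500 strongest peaks the counts are 20 and 20.

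The largest set of shared regions was common to both genotypes. All 8 libraries had a call at 315 union regions (19.2%), and none of these held a combined-list peak or an H3K27ac peak, each of which allows a share of up to 0.952%. Highly enriched ones lay 737078 bp from EMB (chromosome 5, 49656258 to 49661970, mean deposited enrichment 39.1-fold) and 1823 bp from AMPD3 (chromosome 11, 10508665 to 10510138, 39.0-fold). These 2 were chosen by enrichment after their values were seen. If the knockout clones lack NKX2-1, calls shared with all of them cannot be credited to its binding. The 315 regions are therefore no evidence of NKX2-1 sites, however high their enrichment. Chromosomes 1 and 10 held 44 of the 315 each and chromosome 4 held 37. At the other end, 641 regions were called in 1 library only.

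On average, libraries of one genotype resembled each other slightly more than libraries of different genotypes. The mean Jaccard index was 0.551 ± 0.0838 (SD of 6 pairs) among knockout libraries, 0.575 ± 0.0282 (SD of 6 pairs) among WT libraries and 0.517 ± 0.0569 (SD of 16 pairs) between genotypes. The difference of 0.0464 was larger than in any other split of the libraries (permutation p = 0.0286, one-sided, the smallest that 35 splits can give, and 0.0857 after adjustment). The adjusted value would be higher without the tests on the combined and WT-only lists, which belong to the same family and use lists made from these libraries. The indices of S36 with the other knockout libraries (0.456 to 0.487) lay below those of all 12 pairs between genotypes without S36 (0.510 to 0.574), and its indices with WT libraries were lower still (0.390 to 0.459). Each of the 8 libraries had a higher mean index with its own genotype than with the other. For WT13 the means were 0.578 and 0.533, and for S36 0.475 and 0.427. The low index with S36 weighed on the mean of WT13. With the other knockout libraries WT13 had 0.563 to 0.574, within its range of 0.559 to 0.599 with WT libraries.

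Measures that do not refer to particular regions did not separate the genotypes. Knockout libraries held 851 ± 57.2 peaks covering 414 ± 17.8 kb and WT libraries 883 ± 183 peaks covering 435 ± 79.4 kb (SD, n = 4 each; exact permutation p = 0.886 for both). Without WT10 the difference in peak number, WT minus knockout, changed sign from 32.2 to −54.8 peaks, and that in covered length from 21.3 to −17.5 kb. H3K27ac overlapped 1.67% ± 2.08 of knockout peaks and 2.93% ± 2.58 of WT peaks (SD, n = 4 each; exact permutation p = 0.486). WT10 had the highest share (6.47%) and S36 the next (4.71%), while S04 had 0.119%. The difference was 1.26 percentage points, against 0.0752 without WT10. Summits within 1 kb of a gene end made up 2.05% ± 1.93 of knockout and 1.35% ± 0.990 of WT peaks (exact permutation p = 0.629, n = 4 each), and summits within genes 11.97% ± 7.97 and 11.2% ± 4.31 (exact permutation p = 0.886, n = 4 each). Both differences changed sign without S36, to 0.252 and 3.19 percentage points higher in WT, and the second also without WT13 (0.672) or WT30 (0.0245). Peaks on other sequences numbered 274 ± 15.5 in knockout and 303 ± 19.4 in WT libraries (SD, n = 4 each; exact permutation p = 0.0571, adjusted 0.129).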

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

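All tests of explanations in this part were chosen, with their thresholds, after the results were seen, and so were the counts of regions found in a single library, the splits for regions in 1 or more libraries and those among stronger peaks. The splits for WT-specific regions and the Jaccard index with all peaks had been planned.

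Clone S36 stood apart from the other 3 knockout clones in the share of summits within 1 kb of a gene end, with 4.93% against 0.831% to 1.35% (gap over range 0.874). It also had 221 regions that no other library shared and that lay over 10 kb from any WT peak, against 8 to 9 in the other knockout clones (0.995), and 24 of the 221 overlapped H3K27ac. Clone WT10 stood apart in the same count, with 172 against 4 to 32 in the other WT clones (0.833). Of these 172 regions, 36 overlapped H3K27ac and 57 held a combined-list peak. In S36, 0 of the 221 held a combined-list peak, which may be fixed by how that list was made. These were 3 gaps among 20 groups of 4 values examined, where chance gives about 1 in 20.

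Among sequences outside chromosomes 1 to 22, X and Y, the unplaced scaffold GL000225.1 held more peaks in every WT library than in any knockout library, with 84.5 ± 4.80 against 64.0 ± 7.44 (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.114 over the 4 such sequences with a mean of 20 peaks or more). KI270336.1 held a mean of 1.5 peaks in WT and 0 in knockout libraries. Peaks fell on 52 such sequences, 1 of which was higher in every knockout library.

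The uneven calling of combined-list peaks, 121 in WT10, 57 in WT28, 35 in WT30 and 7 in WT13, could come from libraries that differ in their power to call the same sites or from clones that bind different sites. Of the 69 combined-list peaks called in WT13, WT28 or WT30, 64 were also called in WT10, but a list that drew most of its signal from WT10 would give this by construction. Among all 164 regions of those 3 clones that lay over 10 kb from a knockout peak, list peaks included, 107 (65.2%) were also called in WT10 and 34.8% were not; among the 96 without a list peak 44 (45.8%) were. The explanations cannot be told apart, since neither share is near what one of them alone would give and depth is unknown. A difference in NKX2-1 occupancy between clones stays open as a biological explanation that these shares do not decide.

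The absence of combined-list peaks from all 4 knockout libraries may reflect loss of NKX2-1 or how the list was made. None of the 315 regions called in all 8 libraries was on the list, nor any of the 1147 union regions with a call in a knockout library. A list from which regions with knockout signal had been removed, for example by using knockout libraries as the control, would look like this. Loss of NKX2-1 alone would not keep the 315 regions off the list. They were called in all 4 WT libraries too, with a mean deposited enrichment of up to 39.1-fold, while list peaks began at 2.58-fold. These values argue against loss of the factor as the only reason for the absence. The absence therefore does not show that loss.

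Of the 370 WT-only regions without a combined-list peak on chromosomes 1 to 22, X and Y, 43.2% lay within 10 kb of a knockout peak, while 200 random placements gave a mean of 0.554% and at most 1.62%. Noise in calling at the edges of background regions that both genotypes share is a candidate explanation for those near a knockout peak. It was not tested for the remainder, and a biological difference at them stays open.

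As for other splits of the libraries, 16 of the 35 gave at least as many regions called in 1 or more libraries of one group and 0 of the other as the 496 WT-only ones (highest other 691), so chance is not excluded for that count. For the 66 WT-specific regions 1 of the 35 splits, the real one, gave as many (highest other 43), and for the difference in Jaccard index of 0.0464 also 1 (highest other 0.0206). That is below a share of 0.05 for both before any adjustment, and the p of the Jaccard difference was 0.0857 after adjustment over 9 tests, so chance is not excluded for it on the adjusted scale. For the 33 knockout-specific regions 4 of the 34 other splits gave as many in one direction (highest 43), and for the 6 regions in all 4 knockout libraries 1 did (highest 6). At a −log10 q of 10 or more, where 22 knockout-specific regions outnumbered 19 WT-specific ones, the highest other split gave 14.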

How the results depend on the processing

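The count of regions in 1 or more libraries against 0 and the settings based on gene ends, gene bodies, nearest genes and random placement of peaks for the gene counts were chosen after seeing the data. Of 149 recomputed values, 119 kept their direction and side of the threshold, or stayed within 1.5 times for counts. This tally includes differences that stayed above the threshold. It also includes calls at combined-list and WT-only regions, whose absence from knockout libraries follows or may follow from how the lists were made. The tally is therefore no measure of how robust the findings are. WT-specific regions numbered 66, and 19 at a −log10 q of 10 or more, 20 among the 500 strongest peaks, 13 at 4 against 0, 170 at 2 or more and 496 at 1 or more. Knockout-specific regions numbered 33, and 20 among the 500 strongest peaks, 6 at 4 against 0, 100 at 2 or more and 415 at 1 or more. The last 3 settings change the counts by construction, while for the stronger peaks the cause was not tested. Leaving out 1 library gave 18 to 79 WT-specific and 11 to 45 knockout-specific regions. In the genotype of the library left out, 3 of the 3 libraries left are then required, which lowers the count. Without WT10, WT28 or WT30 this requirement includes a call in WT13, and the WT values were then lowest. WT13 had a call at 32 of the 66 regions, against 61 for WT10, 59 for WT28 and 59 for WT30. Without WT13 itself, 47 WT-specific regions remained. When all but 1 of the libraries left sufficed, a definition that is looser than the main one, the counts without WT13 were 154 and 36 and without C15 72 and 75. WT-specific regions then numbered 78 without WT10, 101 without WT28 and 139 without WT30.

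Leaving out 1 library, the difference between genotypes (WT minus knockout) ranged from −54.8 to 79.2 peaks and from −17.5 to 38.4 kb, both reversed without WT10. It ranged from 0.0752 to 2.27 percentage points for H3K27ac overlap, from −1.16 to 0.252 for gene ends (reversed without S36) and from −2.63 to 3.19 for gene bodies (reversed without S36 at 3.19, WT13 at 0.672 and WT30 at 0.0245). Combined-list peaks called ranged from 15.8 to 33.97 percentage points and WT-only regions from 25.4 to 45.5; without any 1 knockout library they stayed at 26.3 and 37.6, but the exact permutation p rose from 0.0286 to 0.0571, since with 3 libraries against 4 a second assignment reaches as large a difference. The difference in Jaccard index ranged from 0.0392 to 0.0545 and kept its p of 0.0286. H3K27ac overlap of the combined list was 15.3%, and 8.43% for the 83 peaks without a WT-only region. No setting brought a gene list past adjustment; the smallest adjusted p ranged from 0.123 to 1, with BCL11B, ETS1 and PTPRC added as nearest genes. That setting had 2 lists at an unadjusted p under 0.05 (T-ALL factors 0.0244, RUNX1 partners 0.0112 by Fisher's exact test), against 0 in the main one.

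Motif settings and distances to transcription start sites were not run, because no genome sequence or strand was used here. No paired analysis was possible because the replicate numbers were given in accession order and tie no WT clone to a knockout clone. Depth is unknown, which limits any reading of a missing peak.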

Other observations

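The comparison of H3K27ac with the gene lists was chosen after the data were seen. The H3K27ac library marked the ends of 3811 protein-coding genes (19.0%), and several of the fixed lists were marked more often. Histone genes had 19 of 20 members with an H3K27ac peak within 1 kb of a gene end (adjusted Fisher's exact p = 3.52e-12 over 11 lists), though these genes are clustered and their peaks are not independent. Cell cycle genes had 17 of 26 (adjusted exact p = 1.06e-06), among them CDK4, CDK6, E2F1 and MKI67, and DNA damage response and repair genes 26 of 47 (adjusted exact p = 1.75e-07), among them ATM, ATR, CHEK1 and BRCA1. None of those 47 repair genes had a combined-list NKX2-1 peak within 10 kb. The single library allows no test between clones.

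T-ALL oncogenic transcription factors had 11 of 24 genes so marked (adjusted Fisher's exact p = 0.00685), among them TAL1, LYL1, LMO1, NKX2-1, MYB, MYC, BCL11B and NOTCH1. RUNX1 and its partners had 7 of 16 (adjusted exact p = 0.0451), including RUNX1, CBFB and ETV6. T-cell development genes had 11 of 36 (adjusted exact p = 0.123), including CD3D, CD3E, CD3G, LCK and ZAP70. NOTCH and MYC targets had 4 of 12 (adjusted exact p = 0.285), apoptosis genes 6 of 16 (adjusted exact p = 0.123) and JAK-STAT genes 6 of 16 (adjusted exact p = 0.123). Lung and thyroid targets had 1 of 24, NKX2-1 itself (adjusted exact p = 0.123), and B-cell and myeloid genes 2 of 20, CEBPB and CD68 (adjusted exact p = 0.403).

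The combined-list peak nearest to BCL11B, a T-cell identity factor, lay 970629 bp from the gene (chromosome 14, 98198494 to 98198772, 4.59-fold), overlapped H3K27ac and was called in 1 WT library. It was singled out after its values were seen.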
